A study of Mus musculus with 16 samples.

How the data were processed

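Gene expression was measured by RNA sequencing of polyadenylated RNA from the atria and ventricles of 8 adult male littermate mice, 16 libraries in all. Per the labels, every mouse carried floxed alleles of Meis1 and Meis2. The 4 idKO mice also carried a transgene for MerCreMer, a tamoxifen-activated Cre recombinase driven by the cardiomyocyte promoter αMHC, and the 4 control mice did not. Hearts were taken 2 weeks after tamoxifen. Per the labels' protocols, libraries were made from 20 ng of RNA and sequenced as single reads of 60 bases.

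Per the submitters' processing notes, the tools were cutadapt and RSEM 1.3.1, with the genome build GRCm38. The tool used for scaling and any filter on low genes are not given in the sources used here. The deposited table holds 16118 genes. Its values are a normalised signal, and the authors' scaling could be read back from the values: each is a whole number of reads plus 0.5, divided by an effective library size and scaled to counts-per-million (CPM). With that step, 100% of the values in each library came out whole within a tolerance of 0.01. The recovered reads per library ran from 13.1 to 21.8 M (mega) reads. The effective size divided by the recovered reads averaged 0.947 in control atria, 0.958 in idKO atria, 0.639 in control ventricles and 0.687 in idKO ventricles. A value is therefore a normalised CPM over effective reads and not a share of the library. Since RSEM estimates need not be whole, the recovered reads are taken as rounded estimates, and reads shared between near-identical genes were divided by that tool. Of the 16118 gene identifiers, 206 had no name in the table, and 202 of these were named from the GENCODE gene table. Gene positions are from the GRCm38 annotation.

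A gene was tested where at least 4 libraries of the fit reached 1 CPM of the summed values. The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with a trended prior, a two-sided test and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. Fold changes are on this log2(value + 1) scale, which understates the change of low genes. The planned design allowed for raw counts, and the limma form planned for normalised values was used because the table holds scaled values. Each chamber was fitted on its own 8 libraries. The interaction (the genotype effect in atria minus that in ventricles) and the comparison of control chambers were fitted on all 16. Single values were compared by exact permutation over the 70 assignments of 4 against 4, two-sided, for which the smallest p is 0.029. For the medians of chamber genes, the chamber calls were made anew in the control group of each of the 70 assignments, so that an assignment and its mirror image differ and the smallest p is 0.014. Standard deviations are over 4 libraries. On simulated reads, the test recovered 34.7% of genes changed by 1.5-fold and 81.8% of those changed by 2-fold in atria (14478 genes tested), with 7 false calls. In ventricles (13136 genes tested) it recovered 59.8% and 76.0%, with 5 false calls. For the interaction (14770 genes tested) it recovered 31.6% and 51.5%, and for the control chambers (14321 genes tested) 46.9% and 69.1%.

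The genes named were fixed by a rule before the data were examined. For each chamber these were Meis1, Meis2 and Meis3, then up to 8 rises and 8 falls with the largest change among called genes whose libraries did not overlap between groups and whose higher group reached 5 CPM. Predicted and clone names were passed over. A few genes that fall under the rule are not reported here; they stay in the fits and in the counts of calls. Up to 4 members with the smallest p were named for each described list, the 10 smallest p for the interaction, and 9 chamber markers. The 40 gene lists, for pathways and for cell types the samples could hold, were also fixed before the data were examined. Lists with at least 3 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. Counts given for fry are those of its directional test.

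The mouse numbers pair atrium and ventricle, since both came from one animal. The deviations of a mouse's atrium and ventricle from their group means correlated at 0.204 to 0.327 across 12945 genes, and each of the 8 mice correlated best with itself. Counts with the mouse as a block are given for ventricles, for the interaction and for the control chambers; in atria the count stayed at 3. Replicates of a group differed by more than sampling noise, with a mean chi-square per gene of 8.08 to 16.8, and none was a repeat of another. Alternatives covered the pseudocount, the filter, rescaling, weights, the prior, DESeq2 1.42.0, edgeR 4.0.16 and limma voom on the recovered reads, and each library or mouse left out. The edgeR fit with TMM, the voom fit, the fit without a pseudocount, the removal of length and GC trends the correlation and split counts without Esr1 and the sign in atria of top ventricular genes over the splits were added after seeing the data. On the recovered reads, edgeR's quasi-likelihood test with TMM called 3 genes in atria and 260 in ventricles.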

Results

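RNA from the atria and the ventricles of 8 mice was sequenced 2 weeks after tamoxifen, giving 4 groups of 4 libraries: control atrium, idKO atrium, control ventricle and idKO ventricle. MEIS1 and MEIS2 are homeodomain transcription factors, and the idKO mice were built to lose both in cardiomyocytes of the adult heart. Reads in genes, in M (mega) reads per library, averaged 16.2 ± 2.60 in control atria, 16.9 ± 3.16 in idKO atria, 19.5 ± 2.92 in control ventricles and 18.5 ± 1.54 in idKO ventricles (SD, n = 4 each). The mice are separate animals, so the spread is between animals. Control mice received no Cre transgene, so any effect of the transgene or of its activation is part of every idKO difference below.

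The targeted genes were read first. In ventricles, Meis2 (chromosome 2, 115863064 to 116065839) fell from 26.8 ± 4.24 to 8.82 ± 0.848 in normalised read count (counts-per-million of effective reads; SD, n = 4), which is 33.0% of the control level (log2 fold change -1.49 ± 0.12 SE, limma adjusted p = 2.0e-05). In atria Meis2 measured 20.0 ± 1.48 in controls and 17.7 ± 1.64 in idKO mice, or 88.8% of control (exact permutation p = 0.057, n = 4 each, adjusted 0.069 over 6 tests; limma adjusted p = 0.966 over all genes). Meis1 (chromosome 11, 18879817 to 19018985) measured 27.3 ± 0.767 and 23.1 ± 2.29 in ventricles, or 84.5% of control. Every idKO ventricle lay below every control for Meis1 (exact permutation p = 0.029, n = 4 each, adjusted 0.043 over 6 tests), but it was not called across all genes (limma adjusted p = 0.236). The 6 tests include Esr1 in both chambers, whose outcome was fixed by the transgene described below. Those tests ease the adjustment, so the adjusted exact p of Meis1 and Meis2 is too favourable. In atria Meis1 measured 28.3 ± 2.86 and 29.7 ± 2.76 (exact permutation p = 0.514, n = 4 each). These gene totals count any transcript left by the deleted alleles, and the labels used here do not name the floxed exons. The related gene Meis3 was not called in either chamber.

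Esr1 (chromosome 10, 4611593 to 5005614), the oestrogen receptor gene whose ligand-binding part is built into MerCreMer, rose in both chambers. It went from 0.967 ± 0.632 to 3099 ± 574 in ventricles (log2 fold change 10.66, limma adjusted p = 6.7e-13) and from 5.02 ± 0.895 to 186 ± 95.5 in atria (log2 fold change 4.84, limma adjusted p = 7.8e-06). The lowest idKO library stood at 98.7 in atria and 2292 in ventricles, and the highest control at 6.17 and 1.84.

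**Figure D1:**
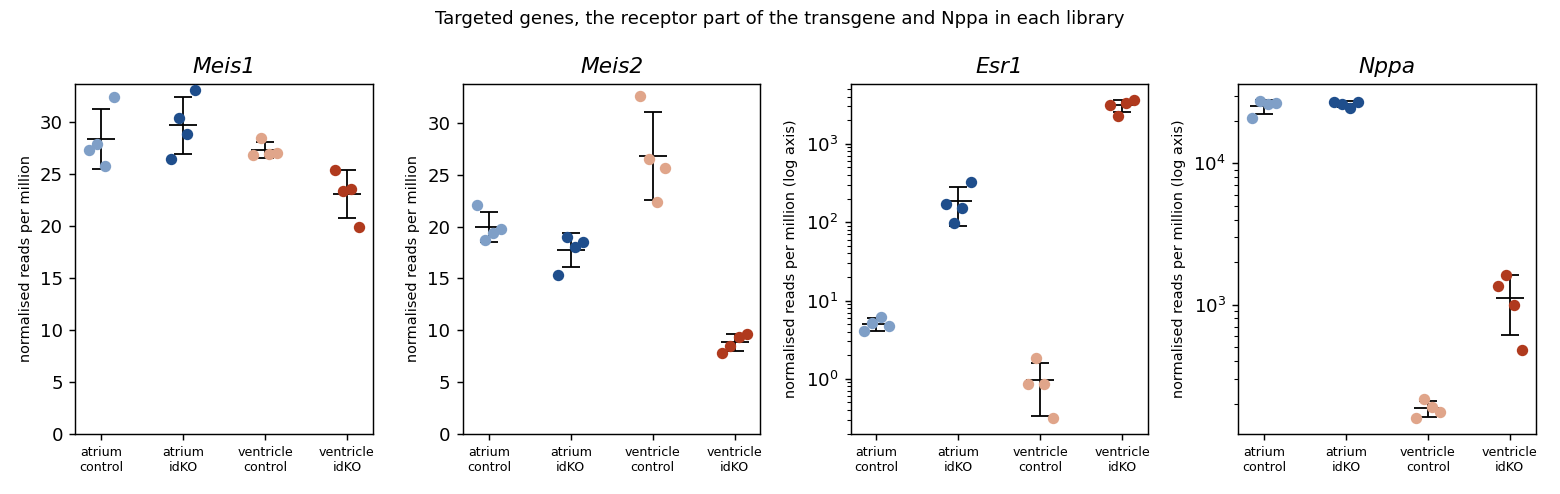
Normalised read count (counts-per-million) of Meis1, Meis2, Esr1 and Nppa in each library (points), with group means and SD (bars, n = 4 per group); the Esr1 and Nppa axes are logarithmic. Meis2 in idKO ventricles averages 8.82 against 26.8 in controls, and Esr1 in idKO ventricles averages 3099 against 186 in idKO atria.

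The ventricle comparison asked which transcripts differ after deletion of Meis1 and Meis2 in adult ventricular muscle. The natriuretic peptide genes Nppa and Nppb, hormones released by strained myocardium, rose from 185 ± 25.0 to 1115 ± 499.9 and from 130 ± 21.3 to 298 ± 47.3 (SD, n = 4). The skeletal actin gene Acta1 rose from 808 ± 210 to 2288 ± 1174. Among genes named by the rule, which passes over predicted and clone names, the largest falls were of Efnb3 and Cenpf. Efnb3, a membrane-bound ephrin ligand, fell from 104 ± 16.5 to 11.0 ± 3.15. Cenpf, a kinetochore protein, fell from 52.0 ± 9.0 to 7.65 ± 1.75. Fhl2, a LIM-domain protein abundant in ventricular muscle, fell from 2206 ± 177 to 793 ± 116. In all, limma called 70 genes higher and 197 lower of 13144 tested, 11 and 28 of them by at least 2-fold.

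The other rises named are the largest among genes whose libraries did not overlap between groups and that reached 5 CPM of the summed values in the higher group, which leaves out Lipo2 (log2 fold change 2.35, described with the atria). They were of Shisa4 (log2 fold change 1.06 ± 0.23 SE), Polr1e, a subunit of RNA polymerase I (0.93 ± 0.11), Ddit4, a stress-induced inhibitor of mTORC1 (0.90 ± 0.17), and Bin1, a membrane-bending protein of the transverse tubules (0.90 ± 0.16). The other falls named by the same rule were of Ttll1, a tubulin polyglutamylase (-1.72 ± 0.09), Gpr22, an orphan receptor (-1.63 ± 0.15), Aqp4, a water channel (-1.24 ± 0.28), and Cntn2, a cell adhesion molecule of the cardiac conduction system (-1.24 ± 0.25). Limma adjusted p ran from 3.1e-07 for Efnb3 and Ttll1 to 0.041 for Aqp4.

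Of 29 tested members of the cardiac ion channel list, 10 fell in ventricles, 1 rose and 18 did not pass, and 14 were lower and 2 higher when adjusted over the list alone. Gja1, which encodes connexin 43 of the gap junctions, fell from 436 ± 62.5 to 201 ± 17.1, Abcc9, the regulatory subunit of the ATP-sensitive potassium channel, from 467 ± 37.4 to 215 ± 32.2, and Kcnh2, a delayed rectifier potassium channel, from 127 ± 14.9 to 69.1 ± 11.6 (SD, n = 4). The list as a whole was lower than other genes (camera adjusted p = 3.1e-08, and adjusted p = 0.206 with an estimated correlation). Of 19 conduction system members, Hcn4, a pacemaker channel, fell from 8.98 ± 2.53 to 3.28 ± 1.37 and Cntn2 from 8.23 ± 1.91 to 3.07 ± 1.46, and 17 did not pass (1 higher and 4 lower adjusted over the list alone). Of 22 calcium handling members, 3 fell: Ryr2, the calcium release channel of the sarcoplasmic reticulum, from 2342 ± 177 to 1485 ± 179, the exchanger gene Slc8a1 (log2 fold change -0.49) and Hrc (-0.34). In that list 1 member was higher and 9 were lower when adjusted over the list alone, with a camera adjusted p = 6.7e-04 and adjusted p = 0.365 with an estimated correlation.

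Contractile genes went both ways. Of 30 sarcomere members, Myom2 rose from 1635 ± 297 to 2388 ± 217 and Tnnt1 from 14.9 ± 1.65 to 22.3 ± 2.69, Nebl fell from 476 ± 30.7 to 324 ± 23.6, and 27 did not pass (2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.825). The list's median log2 fold change was -0.04 and its mean 0.04, so that they differ in sign. Of 20 intercalated disc members, Gja1 and the catenin gene Ctnna1 (874 ± 44.1 to 602 ± 12.2) fell and 18 did not pass (2 higher and 4 lower adjusted over the list alone). Of 18 members of the myocardial stress list, Nppa, Nppb, Acta1 and Tnfrsf12a rose and none fell (7 higher adjusted over the list alone, camera adjusted p = 2.4e-07, and adjusted p = 0.206 with an estimated correlation).

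Of 15 tested genes of ventricular identity, Fhl2, Mpped2, Kcnip2, Lbh and Irx4 fell in ventricles, 0 rose, and 10 did not pass (Irx4 was named after its values were seen). Mpped2 went from 23.9 ± 1.14 to 13.9 ± 1.10 and Kcnip2, a subunit of the transient outward potassium channel, from 267 ± 15.2 to 184 ± 29.5. Adjusted over the list alone, 10 were lower and 1 higher (camera adjusted p = 6.1e-08, and adjusted p = 0.206 with an estimated correlation). Of 14 atrial identity genes tested in ventricles, Nppa rose and 13 did not pass (1 higher and 1 lower adjusted over the list alone).

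In ventricles all 41 respiratory chain members and all 21 members of the tricarboxylic acid cycle list had negative log2 fold changes, with medians of -0.18 and -0.17. Over all genes, 2 of each passed: Cox7a1 (1011 ± 76.8 to 794 ± 70.9) and Cox5b, and Pdhb (1015 ± 39.1 to 833 ± 42.8) and Idh3a. Adjusted over the list alone, 30 respiratory chain and 16 tricarboxylic acid cycle members were lower. The camera adjusted p of the respiratory chain list was 2.7e-18, and adjusted p = 0.362 with an estimated correlation. For the tricarboxylic acid cycle list it was 7.3e-11, and adjusted p = 0.281 with an estimated correlation. The share of reads from mitochondrial genes was 30.9 ± 0.742% in control and 29.0 ± 1.13% in idKO ventricles (exact permutation p = 0.086, n = 4 each). Of 33 fatty acid oxidation members, 1 fell (Etfa), 1 rose and 31 did not pass (1 higher and 5 lower adjusted over the list alone). Of 31 members of the glycolysis and hypoxia list, Pfkp and Hif1a rose, and Slc2a4, the insulin-responsive glucose transporter, Pfkfb1, Ldhb and Pkm fell (2 higher and 10 lower adjusted over the list alone). Ldhb and Pkm were named after their values were seen. The camera adjusted p was 5.6e-05 for fatty acid oxidation and 0.0070 for glycolysis and hypoxia, and adjusted p = 0.416 with an estimated correlation for both.

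Of 19 macrophage genes in ventricles, Lyz2 rose from 151 ± 6.98 to 196 ± 22.8 (3 higher adjusted over the list alone), and of 27 interferon response genes Iigp1 and Oas2 rose (3 higher adjusted over the list alone). Of these 27 interferon genes, 25 were positive (camera adjusted p = 4.3e-07, and adjusted p = 0.358 with an estimated correlation). Of 11 mesothelial genes, Msln fell from 8.45 ± 1.52 to 3.37 ± 1.32 (4 lower adjusted over the list alone). None of 17 fibroblast, 20 endothelial, 8 endocardial or 30 extracellular matrix genes passed over all genes, but 16, 18, 8 and 29 of them had positive log2 fold changes, with medians of 0.21, 0.08, 0.19 and 0.23, while the respiratory chain and tricarboxylic acid cycle lists lay below 0 as given above. Adjusted over the list alone, 2 endocardial genes were higher. Camera gave adjusted p = 0.0129 for endothelial and 0.0121 for endocardial genes, and adjusted p = 0.365 and 0.206 with an estimated correlation. The camera calls for extracellular matrix (adjusted p = 9.7e-07), fibroblasts (1.7e-04) and macrophages (1.5e-04) gave adjusted p = 0.416, 0.416 and 0.206 with an estimated correlation. Of the 24 tested p53 and DNA damage genes, none passed (camera adjusted p = 0.859). Across lists in ventricles, camera with the preset correlation called 17 of 36, and none was called with an estimated correlation. The third test, fry, called 9 of 36, of which camera with the preset correlation also called 7. These 7 were cardiac ion channels, myocardial stress, respiratory chain, tricarboxylic acid cycle, ventricular identity, endocardial cells and macrophages (fry adjusted p from 0.0020 to 0.032). The ventricular counts were 35 higher and 97 lower without control replicate 4, 40 and 118 without control replicate 3, 35 and 122 without idKO replicate 2, and 44 and 139 without idKO replicate 3. Without idKO replicate 4 the counts rose to 103 and 256. DESeq2 on the recovered reads called 195 higher and 342 lower, limma without a trended prior 19 and 70, a joint fit of both chambers 112 and 241, and that fit with the mouse as a random effect 119 and 253. Of 25 alternatives, the call was lost in 14 for Hrc and Tnfrsf12a, 13 for Cox5b, 12 for Idh3a, 9 for Lyz2 and Oas2, 8 for Cox7a1, 6 for Myom2, Pdhb and Tnnt1, and 4 for Acta1, Ddit4 and Iigp1. Of 24 alternatives, it was lost in 13 for Aqp4, 8 for Shisa4 and 5 for Cntn2.

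**Figure D2:**
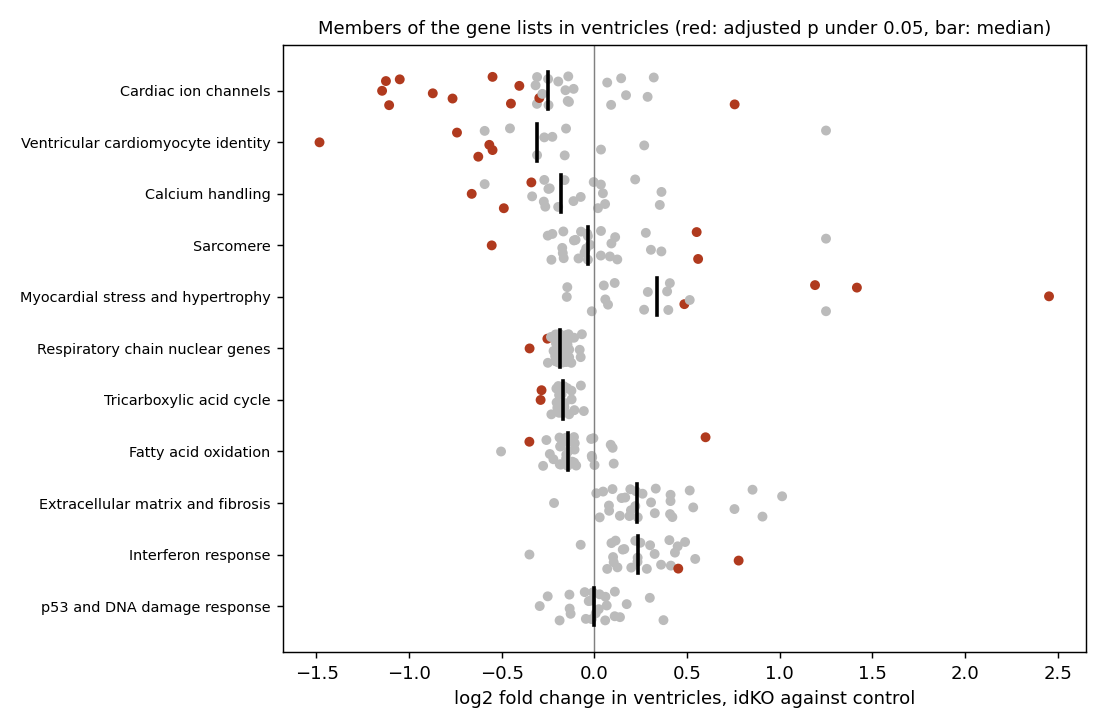
Log2 fold change in ventricles, idKO against control (horizontal axis), of each tested member of 11 gene lists (points; red passes an adjusted p of 0.05), with the list median as a bar. All 41 respiratory chain members lie below 0, and Nppa is the rightmost point at 2.45.

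The atrium comparison asked the same of atrial muscle. Only 3 of 14523 genes passed in limma and all 3 rose: Esr1, Prkg1 and Lipo2. Prkg1, which encodes the cGMP-dependent protein kinase, rose from 12.9 ± 1.53 to 32.6 ± 2.35 (log2 fold change 1.28 ± 0.10 SE, limma adjusted p = 2.4e-04), and Lipo2, a lipase family gene, from 0.648 ± 0.196 to 5.29 ± 1.46 (1.91 ± 0.21, limma adjusted p = 0.0050). Both also rose in ventricles (Prkg1 by 0.77, Lipo2 by 2.35 on the log2 scale). Both lie on chromosome 19, Prkg1 at 30564489 to 31765033 and Lipo2 at 33719670 to 33751359. No gene fell in limma, while 670 genes had an unadjusted p under 0.05, which is 4.61% of those tested. The libraries of the groups did not overlap for 2.82% of genes, against 2.86% by chance. DESeq2 on the recovered reads called 10 higher and 2 lower, edgeR 3 and 0, and voom 2 and 0, where Lipo2 had an adjusted p of 0.052. Without any 1 idKO atrium Lipo2 fell under the filter on low values and was not tested, and 1 gene was lower without idKO replicate 3 or 4.

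No member of any list was called in atria over all genes by limma (counts by the other tools are given above for all genes). The median log2 fold change was 0.15 for 20 endothelial genes (0.24 for Tie1, 0.25 for Pecam1) and 0.22 for 17 fibroblast genes. It was -0.07 for 32 ion channel genes (Kcnh2 at 232 ± 19.7 and 195 ± 19.6), and 0 members of these 3 lists passed when adjusted over the list alone. Camera with the preset correlation gave adjusted p = 5.4e-07, 3.3e-07 and 0.0026 for these lists, and adjusted p = 0.245, 0.563 and 0.563 with an estimated correlation. Lymphocyte genes had a median of -0.94 over 10 genes (adjusted p = 3.5e-05, and adjusted p = 0.563 with an estimated correlation), but the SD between idKO atria exceeded the mean for 5 of them, the median ratio of SD to mean was 0.429 in control and 1.05 in idKO atria, and the mean score of the list had an exact permutation p = 0.171 (n = 4 each). Camera called 13 of 38 lists in atria, and none was called with an estimated correlation or with fry's directional test. For the endothelial list, 19 of 20 members were positive. Its mean score had an exact permutation p = 0.029 (n = 4 each), not adjusted over the 38 lists. Fry's test without direction gave this list an adjusted p = 0.041. Among the 13 were tricarboxylic acid cycle (19 of 21 negative, camera adjusted p = 0.0032) and respiratory chain (35 of 41 negative, camera adjusted p = 0.023). Interferon response was another (24 of 29 positive, camera adjusted p = 7.0e-05). With an estimated correlation the camera adjusted p of these was 0.675, 0.797 and 0.563.

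The interaction tested whether the genotype effect differed between chambers. It did for 44 of 14871 genes, 40 with a more positive effect in atria and 4 with a more positive effect in ventricles. Meis2 itself differed by 1.33 ± 0.16 on the log2 scale (limma adjusted p = 2.7e-04), Efnb3 by 2.83, Cenpf by 2.21, Ttll1 by 1.73, Fhl2 by 1.25, Abcc9 by 1.19, Rit1, a small GTPase, by 0.90 and Entpd5 by 0.90. The 4 with the larger rise in ventricles were Esr1, Nppa, Nppb and Polr1e, with differences of -5.82, -2.39, -1.18 and -0.85. Abcc9 measured 49.5 ± 5.58 and 51.6 ± 5.23 in control and idKO atria, and Nppa 25144 ± 2986 and 26132 ± 1173. With the mouse as a block the count was 102 as a fixed effect (79 more positive in atria and 23 in ventricles) and 71 as a random effect (54 and 17), and DESeq2 on the recovered reads called 86 (64 and 22). All 44 were among the calls of each of these fits, and the division by direction was less uneven there than 40 to 4. The count was 24, 24 and 23 without control mouse 2, 3 or 4, and 19 and 23 without idKO mouse 2 or 3.

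**Figure D3:**
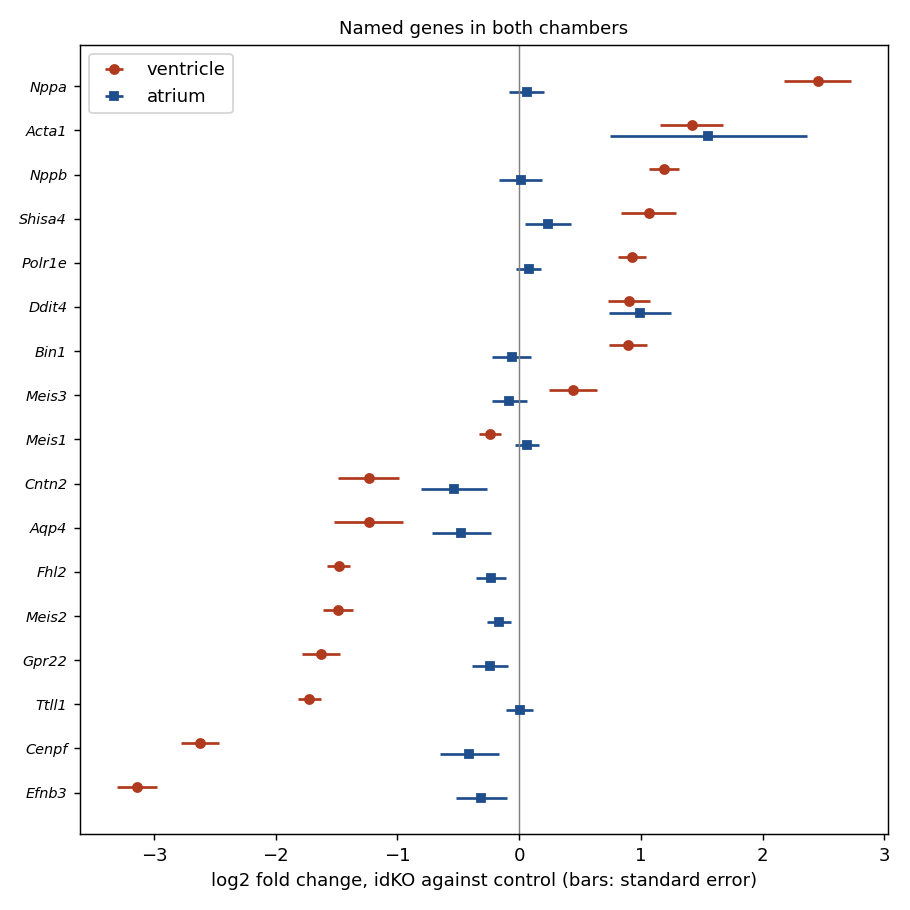
Log2 fold change, idKO against control (horizontal axis), of genes named by rule in ventricles, in ventricles (circles) and atria (squares); bars are standard errors from limma. Nppa stands at 2.45 in ventricles and 0.06 in atria, and Efnb3 at -3.14 and -0.31.

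Control atria and control ventricles differed in 8468 of 14871 genes, 4201 higher in atria and 4267 higher in ventricles. With the mouse as a block they differed in 8955 genes as a fixed effect (4430 and 4525) and in 9120 as a random effect (4546 and 4574). Myl7 and Myl4, the atrial myosin light chains, measured 5077 ± 434 and 6597 ± 703 in control atria against 11.2 ± 4.23 and 16.3 ± 4.14 in control ventricles. Sln, a regulator of the calcium pump, measured 1835 ± 72.3 and 3.25 ± 1.59, Nppa 25144 ± 2986 and 185 ± 25.0, and Bmp10, an atrial growth factor, 1973 ± 295 and 0.408 ± 0.0628. Myl2 and Myl3, the ventricular light chains, measured 13.9 ± 13.7 and 97.7 ± 5.34 in atria against 8396 ± 316 and 7360 ± 381 in ventricles, and the transcription factor genes Irx4 and Hey2 were also higher in ventricles (38.7 ± 2.87 and 6.08 ± 0.551, limma adjusted p = 1.4e-15 and 0.0023).

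Genes that prefer a chamber in controls were then followed across genotypes. In ventricles, the median log2 fold change was 0.07 for atrial genes and -0.07 for ventricular genes (exact permutation of the mice, p = 0.014 and 0.043, n = 4 each, adjusted 0.057 and 0.086 over 4 medians). In atria both medians were -0.01 (exact permutation p = 0.757 for both, n = 4 each). The same control libraries entered both the chamber calls and the genotype effect. With the calls made in idKO libraries, the ventricular medians were 0.01 and -0.04 (exact permutation p = 0.757 and 0.314, n = 4 each). For chamber genes of at least 2-fold in controls, they were 0.11 and -0.13 (exact permutation p = 0.086 and 0.014, n = 4 each, adjusted 0.171 and 0.057). At that cut in idKO libraries they were 0.02 and -0.06 (exact permutation p = 0.786 and 0.400, n = 4 each).

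Across the 12945 genes tested in both chambers, atrial and ventricular effects correlated with Pearson's r = 0.379 and Spearman's rho = 0.263, where genes are not independent replicates and both chambers come from the same mice. Of the 35 splits of the 8 mice, 2 gave a Pearson's r as large and 8 a Spearman's rho as large (permutation p = 0.057 and 0.229), and the median over the other splits was 0.289 and 0.207. The covariance was 0.0163 against a median of 0.0082 in other splits. Without Esr1, Pearson's r was 0.320 and 7 splits were as large. All 3 genes called in atria were called in ventricles. Esr1 is fixed by the transgene and both chambers come from the same mice, so independent lists give no fair measure for this overlap. Of the 267 genes called in ventricles, 259 were tested in atria, and 196 of these (75.7%) had the same sign there, against 59.6% of all genes. In a test chosen after the data were seen, the 267 genes with the smallest p in ventricles in each split of the mice gave a share as large in 12 of 35 splits (permutation p = 0.343, median of the other splits 73.4%), so the shared sign was within what other splits gave, with both chambers from the same mice.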

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

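Of the tests below, the counts over other splits of the mice were planned, and those on atrial tissue, cardiomyocyte share, the transgene, the insertion neighbourhood, Meis2 loss, atrial spread and atrial deletion, and the split counts without Esr1, were chosen only after the result was seen.

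The genes called in ventricles (267) exceeded those of any other split of the 8 mice. Of the 35 splits 1, the real one, gave as many, and the highest other gave 3. Every other split mixes idKO and control mice, which widens the spread of genes that differ, here and in the split counts below. The share of splits is therefore read and not the size of the gap. Chance is argued against, at the smallest share that 35 splits can give. More atrial tissue in the idKO ventricle samples is argued against. Over 24 genes at least 20-fold higher in control atria, the median share of the gain that Nppa implies was -0.0053. The bootstrap interval over these genes was -0.0459 to 0.0296, and leaving out 1 library at a time gave -0.0227 to 0.0012. Myl7 measured 11.2 and 9.33 in control and idKO ventricles. A lower share of cardiomyocyte RNA as the whole cause is argued against. The sarcomere list median was -0.0368 beside a median of -0.48 for called falls, with a bootstrap interval over the 30 members of -0.0936 to 0.0597. Both bootstrap intervals resample genes and do not measure the spread between mice. As a part of the cause of the small shifts, a lower cardiomyocyte share stays open. There 16 of 17 fibroblast genes were positive and all 41 respiratory chain genes negative. Activity of the transgene product cannot be told apart from the loss of Meis1 and Meis2, because the controls lack the transgene; the count of called p53 genes, 0 in limma, does not decide it. Deletion of Meis1 and Meis2 stays open as the biological explanation.

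Prkg1 and Lipo2 rose in both chambers and lie 1.95 Mb apart on chromosome 19. An effect on the genes around the transgene insertion may account for it, as a hypothesis: this transgene is known to lie at A1cf, between the pair, and the other 52 tested genes within 5 Mb had a median absolute log2 fold change of 0.12 against 0.08 in random runs of neighbouring genes (percentile 98.98). Of these 52, 3 were called in ventricles, Ide, Cdc37l1 and 4430402I18Rik, all lower. In ventricles and atria the log2 fold change was -0.64 and -0.60 for Ide, -0.29 and -0.01 for Cdc37l1, and -0.69 and 0.06 for 4430402I18Rik. Cdc37l1 and 4430402I18Rik thus did not change in both chambers as Prkg1 and Lipo2 did. A strain haplotype carried along with the transgene could also give larger changes among the neighbouring genes and was not tested. A response to the loss of Meis2 transcript cannot be told apart, since the pair was picked for rising in both chambers: the ratio of atrial to ventricular change was 0.812 ± 0.111 (SE) for Lipo2 and 1.66 ± 0.370 for Prkg1, against a median of 0.156 over 259 genes called in ventricles.

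Few genes were called in atria: 3, with 1 of 35 splits giving as many and 2 in the highest other, but Esr1 is fixed by the transgene, and without it 2 were called and 7 of 35 splits gave as many (2 in the highest other), so chance may account for a count of that size. Between chambers 44 differed (1 of 35 splits, highest other 1) and 43 without Esr1 (highest other 1). Chance is argued against there, at the smallest share that 35 splits can give. A larger spread between atrial libraries cannot be told apart as a part of the cause: for 38.2% of 259 genes called in ventricles (99) the atrial 95% interval lay below 0.5 of the ventricular change, and the median SE was 0.10 in atria and 0.09 in ventricles. Less deletion in atrial cardiomyocytes may contribute, since the log2 fold change of Meis2 was less negative in atria (difference 1.33), but Meis2 RNA from other cells keeps this open. Esr1, whose ligand-binding part is in MerCreMer, was also lower in idKO atria (186) than in idKO ventricles (3099). How far this changed the deletion was not tested. Ventricular tissue in the atrial samples was not tested either. Myl2 measured 13.9 ± 13.7 in control and 58.6 ± 46.1 in idKO atria, and Myl3 97.7 ± 5.34 and 124 ± 41.6. Neither was called there. A different need for MEIS1 and MEIS2 in the chambers stays open and was not tested.

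The count between control atria and control ventricles was 8342 in the fit of the 8 control libraries alone. Only the real one of 35 splits reached it, with 2 in the highest other. The highest of the others that part every pair of chambers gave 0. Every other split mixes atria and ventricles within a group, which widens the spread there. The 2 chambers of a mouse are also paired, and only 8 splits part every pair. So few splits cannot give a share under 0.05, and the split counts cannot decide on chance for this comparison.

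The genotype effect differed between chambers by limma's interaction test for 18 named genes, given as log2 effect in atria minus that in ventricles. The differences were 1.33 for Meis2, -5.82 for Esr1, -2.39 for Nppa, -1.18 for Nppb, -0.85 for Polr1e and 2.83 for Efnb3. They were 2.21 for Cenpf, 1.73 for Ttll1, 1.39 for Gpr22, 1.25 for Fhl2, 1.19 for Abcc9 and 1.12 for Gja1. They were 0.52 for Nebl, 0.39 for Ctnna1, 1.14 for Mpped2, 0.90 for Rit1, 0.90 for Entpd5 and 0.99 for Irx4. Mpped2 and Irx4 fell under the filter on low values in the atrial fit and were not tested there. Irx4 measured 0.076 ± 0.083 in control and 0.390 ± 0.194 in idKO atria, near the floor. Its difference therefore rests in part on very few atrial reads.

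In 19 of 313 gene and group pairs 1 library stood apart from the other 3, where about 15.65 would by chance; the values are the gap to the nearest library over the range of the group. In control atria they were 0.972 for Scn4a (replicate 4), 0.868 for Ddit4 (replicate 4), 0.875 for Gja1 (replicate 1), 0.870 for Dsp (replicate 4) and 0.877 for Dlat (replicate 2). In idKO atria they were 0.870 for Flt1 (replicate 1), 0.893 for Acta1 (replicate 3), 0.886 for Hcn4 (replicate 4), 0.858 for Tnnt1 (replicate 4) and 0.871 for C1qb (replicate 2). In control ventricles they were 0.923 for Meis1 (replicate 2), 0.862 for Pecam1 (replicate 3), 0.848 for Cacna1h (replicate 4), 0.886 for Idh3a (replicate 2), 0.841 for Dlat (replicate 2) and 0.830 for Slc2a4 (replicate 3). In idKO ventricles they were 0.853 for Scn4b (replicate 4), 0.879 for Etfdh (replicate 2) and 0.892 for C1qc (replicate 1).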

How the results depend on the processing

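The tests with edgeR and TMM, with voom, without a pseudocount, with length and GC trends removed and without Esr1 were chosen only after the result was seen. In ventricles, the counts higher and lower (70 and 197) became 30 and 118 with no filter, 19 and 70 without a trended prior, 195 and 342 with DESeq2, 11 and 28 at 2-fold and 151 and 316 at an adjusted p of 0.1. The counts were 112 and 241 in a joint fit and 119 and 253 with the mouse as a random effect. In atria DESeq2 called 10 and 2. The interaction count (44) was 24 without a trended prior, 86 with DESeq2, and 102 and 71 with the mouse as a fixed or random effect. The cause was not tested, apart from the stricter or looser thresholds. With a library or mouse left out, the ranges were 2 to 4 higher and 0 to 1 lower in atria, 35 to 103 higher and 97 to 256 lower in ventricles, and 19 to 39 for the interaction. Fewer samples were fitted there, but the highest ventricular counts (103 and 256) came without idKO replicate 4. With chamber calls made in idKO libraries, the median of atrial genes in atria turned from -0.01 to 0.0232. Of the values of the reported genes under alternatives in ventricles, 1450 kept direction and side of the threshold, 150 lost the call and 40 gained it, with 0 reversed. In atria 329 kept both, 1 (Lipo2 under voom) lost the call, and all 230 interaction and 206 chamber values kept both. With length and GC trends removed, 262 of 267 ventricular calls were kept. Lipo2 could not be tested with the stricter filter or without an idKO atrium. All 17 ventricular and 13 atrial camera calls were lost with an estimated correlation; with fry, 10 and 13 were lost. In simulated reads 34.7% of 1.5-fold changes were recovered in atria and 59.8% in ventricles, so changes of that size can be missed. At 2-fold the order was the other way, with 81.8% in atria and 76.0% in ventricles.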

Other observations

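The tests of the antigen presentation genes and H19 were chosen only after the result was seen; the fit on the means of each mouse was added after the fits of each chamber had been seen, with the prediction for its splits written before they were run.

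Genes that present antigen to T cells, in 18 chosen after their values were seen, were examined in both chambers. In ventricles 4 rose: H2-Aa, a class II chain, from 60.5 ± 8.67 to 95.8 ± 14.7, H2-Ab1, its partner, from 49.4 ± 6.26 to 80.6 ± 13.4, Cd74, the invariant chain, from 127 ± 12.9 to 183 ± 33.4, and B2m, the light chain of class I, from 153 ± 21.1 to 222 ± 38.6 (SD, n = 4). In atria limma called 0 of these 18, and 17 had positive log2 fold changes in each chamber. Macrophage genes, from cells that carry class II chains, were also mostly positive: 16 of 19 in ventricles (camera adjusted p = 1.5e-04, and adjusted p = 0.206 with an estimated correlation) and 15 of 20 in atria (camera adjusted p = 0.124). A change in the number of such cells was not tested apart from a change within them. H19, a long noncoding RNA also chosen after its values were seen, measured 16.3 ± 4.09 and 25.9 ± 3.63 in ventricles (limma adjusted p = 0.044) and 68.4 ± 14.0 and 119 ± 16.1 in atria (limma adjusted p = 0.311).

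With both chambers averaged within each mouse, limma called 33 of 12945 genes, 10 higher and 23 lower. Of the 35 splits of the mice, 1, the real one, gave as many and the highest other gave 3. Chance is argued against, at the smallest share that 35 splits can give. The ventricular libraries enter these means, so the count is not independent of the ventricular calls. The called genes included Esr1, Lipo2, Prkg1, Nppa, Pfkp, H2-Aa (log2 fold change 0.53) and H2-Ab1 (0.52) among those higher, and Meis2, Efnb3 and Ttll1 among those lower. A call on the mean does not show a change in both chambers. In atria and ventricles the log2 fold change was 0.06 and 2.45 for Nppa and -0.16 and -1.49 for Meis2. It was -0.31 and -3.14 for Efnb3 and 0.004 and -1.72 for Ttll1. Prkg1 rose in both (1.28 and 0.77).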
